A study of Homo sapiens with 10 samples.

How the data were processed

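Human embryonic stem cells carrying a reporter in the GATA3 gene (a clone of the line G3KI) were, per the labels, grown over mouse fibroblast feeders in serum replacement medium containing basic FGF, then moved to Matrigel and exposed from the next day to A83-01 at 1 µM with PD173074 at 0.1 µM. Cells were taken at days 0, 1, 2, 4 and 8. Total RNA was extracted with RNeasy micro columns and made into TruSeq Standard mRNA libraries, which select polyadenylated RNA. The 10 libraries formed 5 groups of 2 by day. The deposited matrix holds TPM values made by the authors, a length-adjusted share of the transcripts of a library, with 2 decimals. Each library's values share a fixed sum, and the matrix gives no counts, so the depth per library is unknown and no counting error can be attached to a value. The submitters' processing notes name STAR 2.6.1d, RSEM and the GRCh38 build. The annotation release, any filter and the strand setting are not given in the sources used here, so genes that overlap on opposite strands cannot be told apart with certainty.

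The matrix has 58825 gene rows, of which 58552 matched GENCODE 29 by Ensembl identifier without its version (47420 with it). GENCODE 29 supplied positions, gene types and transcript lengths. Where a symbol stood on more than 1 row (149 symbols), the row with the higher mean TPM stood for it in the lists. A gene was tested when it had a TPM of at least 1 in at least 2 of the 10 libraries, which left 18773 genes (31.9%), and 12050 genes were above 1 TPM in every library. Values were analysed as log2(TPM + 1). A linear model with a mean per day was fitted to all 10 libraries with limma 3.58.1 in R 4.3.3, with moderated variances that follow a trend with the mean level (3.20 prior and 5 residual degrees of freedom). The 5 contrasts were day 1 against day 0, day 2 against day 1, day 4 against day 2, day 8 against day 4 and day 8 against day 0. P-values counted changes in either direction and were adjusted by Benjamini and Hochberg over the genes of a contrast, and a gene was called at an adjusted p under 0.05. Change over any of the days was tested with the moderated F statistic. A gene counted as transient when day 1, 2 or 4 passed in the same direction against day 0 and against day 8. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

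Gene lists were tested with camera, from limma, at a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast, for lists with at least 3 tested genes. The 30 lists were pluripotency, naive-state pluripotency, early ectoderm and trophoblast factors (GATA, TFAP2, homeobox and grainyhead genes with HAND1 and TBX3), amnion, syncytiotrophoblast, pregnancy-specific glycoproteins, cytotrophoblast, extravillous trophoblast, keratins, epithelial junctions, BMP targets, Activin and Nodal targets, FGF and ERK targets, WNT targets, primitive streak and mesoderm, endoderm, neuroectoderm, neural crest, mesenchyme and fibroblast, endothelium and blood, HOX genes, proliferation, p53 targets and cell cycle arrest, glycolysis, cholesterol synthesis, interferon-stimulated genes, MHC class I, imprinted genes, stress response and mitochondrially encoded mRNAs. The contrasts, lists, thresholds, alternatives and the rule for named genes were set before the data were examined. That rule names GATA3 in every library first, then a panel of genes at each day (POU5F1, NANOG, SOX2, CDX2, TFAP2A, ISL1, GABRP, KRT7, CGA, CGB5, SDC1, ERVW-1, TP63 and HLA-G). It then takes, per contrast, the 8 highest and 8 lowest log2 changes among called genes with a mean of at least 10 TPM in the higher day. Per list it takes up to 4 called members with the largest change and called members that go against the list, and per intermediate day 8 transient genes in each direction. The text gives a part of the genes so chosen, and says where a gene was chosen in another way.

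The alternatives tried were pseudocounts of 0.1 and 0.5, no filter on low values, a mean TPM of at least 5, median-of-ratios scaling, quantile normalization, rescaling without mitochondrially encoded genes, no variance trend, an absolute log2 change of at least 1, a fit to the compared days alone, the replicate number as a block, leaving out each library in turn, and for lists fry and camera with an estimated inter-gene correlation. Leaving out each library for the values of named genes was added after the data were seen. The procedure was tested on simulated data for day 8 against day 0, drawn around each gene's mean over the libraries with its fitted spread.  With changes set in 100 genes each, a log2 change of 1 was found for 54 and a log2 change of 2 for 83, and for 80.8% and 100% of those with a mean of at least 10 TPM, while 11 unchanged genes were called (7.43% of the calls). In the data far more genes differed, with 13187 called at day 8 against day 0. That loosens the adjusted threshold, so these shares need not carry over to the data. In 15 of the 30 lists some tested members were under 1 TPM in every library of days 0 and 1 and passed the level filter only through later days, so where such a list also has members left untested, its count of rises leans on that filter. The rule for named genes leaves out entries with no symbol, clone-style names, marked pseudogenes, X-inactivation transcripts and Y-linked genes.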

Results

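Transcript levels were measured by RNA sequencing in human embryonic stem cells carrying a reporter in the GATA3 gene, at days 0, 1, 2, 4 and 8 of exposure to A83-01, an inhibitor of the ALK4, ALK5 and ALK7 receptors of the Activin, Nodal and TGF-beta pathways, with PD173074, an inhibitor of FGF receptors. Each day had 2 libraries, 10 in all. The design followed the transcriptome along a trophoblast-like differentiation, so each day was compared with the day sampled before it, and day 8 with day 0. Values were in TPM, the length-adjusted share of a library's transcripts, which are relative to a fixed sum per library and keep no record of depth, so the depth behind each value is unknown. Between 22935 and 26636 rows of the gene table were above 0 per library. Of the 18773 genes tested, 15036 (80.1%) differed between days by limma's moderated F test. The first principal component held 67.4% of the variance and ran from day 0 to day 8, and the second held 13.5% and set day 2 and day 4 apart from day 0 and day 8. Pearson's r between the 2 libraries of a day, across genes, lay between 0.981 and 0.990, and genes are not independent replicates. Beside a TPM, ± is the SD over 2 libraries (n = 2 per day). Log2 changes are on the log2(TPM + 1) scale, which understates the change of genes at low level, and their ± is limma's SE. Every list called by camera lost its call with an estimated inter-gene correlation, and that p, given beside each, was the highest over the alternatives tried. Nothing in the labels says that both libraries of a day came from separate cultures, so p-values measure only the spread between these libraries, which can be technical.

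**Figure D1:**
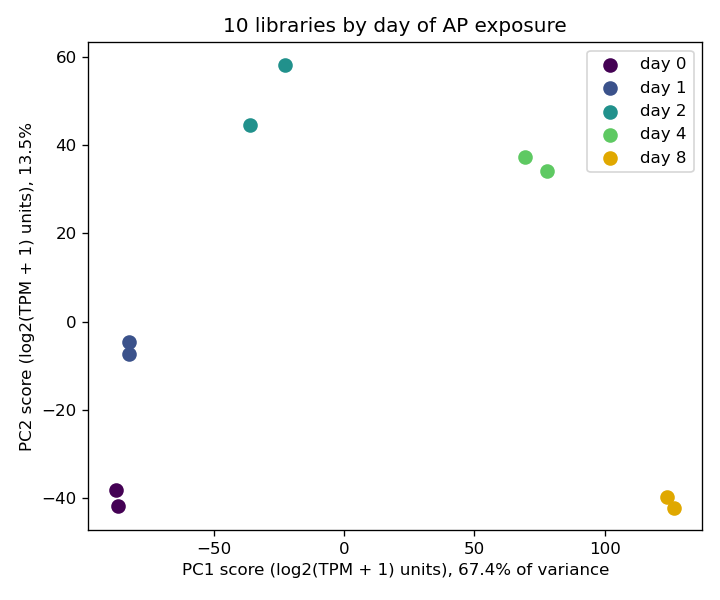
Principal components of log2(TPM + 1) over the 18773 genes tested, with the score on the first component (67.4% of the variance) on the x axis and on the second (13.5%) on the y axis. Each point is a library coloured by day, and both libraries of a day lie closer to each other than to any library of another day.

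GATA3, a zinc-finger factor of trophoblast and amniotic lineages and the gene that carries the reporter (ENSG00000107485, chromosome 10, 8045378 to 8075203, GRCh38), was read in each library first. Its level was 1.19 and 0.560 TPM at day 0, 6.30 and 6.70 at day 1, 170.3 and 207 at day 2, 515 and 568 at day 4, and 695 and 702 at day 8. The rise passed at day 1 (log2 change 2.02 ± 0.16), at day 2 (4.65 ± 0.16) and at day 4 (1.52 ± 0.16). From day 4 to day 8 the change was 0.37 ± 0.16 and did not pass (limma adjusted p = 0.0893). It passed after median-of-ratios scaling (0.57, adjusted p = 0.0186) and without day 0 replicate 1 (adjusted p = 0.0219) or day 0 replicate 2 (adjusted p = 0.0218). Over 13 alternatives that p ran from 0.0186 to 0.297.

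POU5F1, NANOG and SOX2, transcription factors that maintain pluripotency, were at 2855 ± 57.7, 143 ± 2.12 and 149.8 ± 19.9 TPM at day 0 and at 14.4 ± 11.96, 0.675 ± 0.700 and 0.640 ± 0.424 TPM at day 8. All 3 fell over that span, with log2 changes of -7.80 ± 0.52, -6.49 ± 0.63 and -6.54 ± 0.21, where that of POU5F1 was -6.91 without day 8 replicate 1 and -8.69 without day 8 replicate 2. SOX2 was at 154 ± 9.87 TPM at day 1 and fell by day 2 to 25.4 ± 5.80 TPM (log2 change -2.57 ± 0.21). NANOG fell to 10.6 ± 2.08 TPM by day 1 (log2 change -3.64 ± 0.63, limma adjusted p = 0.00607), a call lost with a pseudocount of 0.1 (adjusted p = 0.0815) and without day 1 replicate 2 (adjusted p = 0.0504). Its p ran from 7.01e-04 to 0.0815 over 13 alternatives. POU5F1 was at 1219 ± 40.4 and 557 ± 169 TPM at days 1 and 2, and neither step passed (log2 changes -1.23 ± 0.52 and -1.16 ± 0.52, limma adjusted p = 0.144 and 0.146). Without day 8 replicate 1 or day 8 replicate 2 both steps of POU5F1 passed, at adjusted p = 0.0446 and 0.0445 for day 1 against day 0 and at 0.0398 for day 2 against day 1, the lowest over 13 alternatives, where the highest were 0.362 and 0.449.

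TFAP2A, a factor of surface ectoderm and trophoblast (chromosome 6, 10393186 to 10419659), climbed from 0.415 ± 0.0354 TPM at day 0 to 78.4 ± 2.02 at day 1 and 479 ± 52.6 at day 8. CDX2, a homeobox factor of early trophectoderm, was at 0.0900 ± 0.0566 TPM at day 1, 11.3 ± 1.65 at day 2 and 0.315 ± 0.205 at day 4. ISL1, a homeobox factor of amnion, peaked at day 2 with 24.8 ± 2.49 TPM, against 0.440 ± 0.113 at day 0 and 0.235 ± 0.0636 at day 8. GABRP, a GABA receptor subunit used as an amnion marker, was highest at day 4, at 611 ± 112 TPM, between 155 ± 46.7 at day 2 and 74.0 ± 15.05 at day 8. KRT7, a keratin of trophoblast and amnion, rose from 22.3 ± 3.20 at day 1 to 680.3 ± 69.6 TPM at day 2. CGA, the alpha subunit of chorionic gonadotropin (chromosome 6, 87085498 to 87095406), was at 0.865 ± 0.106 TPM at day 2, 3509.7 ± 533 at day 4 and 12036 ± 1019.6 at day 8. At day 8 it made up 1.28% and 1.13% of the TPM of both libraries. CGB5, a gene of the beta subunit, was at 17.1 ± 13.6 TPM at day 4 and 650.1 ± 31.7 at day 8. Its reads are hard to tell from those of CGB3 and CGB8. SDC1, a syndecan of the syncytiotrophoblast surface, stood at 7.79 ± 1.34 TPM at day 2 and 428 ± 72.6 at day 4. ERVW-1, the envelope gene of syncytin-1, was at 0.335 ± 0.219 and 359 ± 99.0. HLA-G, a class I molecule of extravillous trophoblast, rose from 4.21 ± 1.19 at day 2 to 122 ± 17.5 at day 4 and 439.9 ± 40.3 at day 8. TP63, a factor of cytotrophoblast stem cells, stayed low, at 0.0550 ± 0.0212 TPM at day 0, 1.67 ± 0.438 at day 2 and 0.920 ± 0.410 at day 8. Its rises from day 1 to day 2 and from day 0 to day 8 passed all the same.

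**Figure D2:**
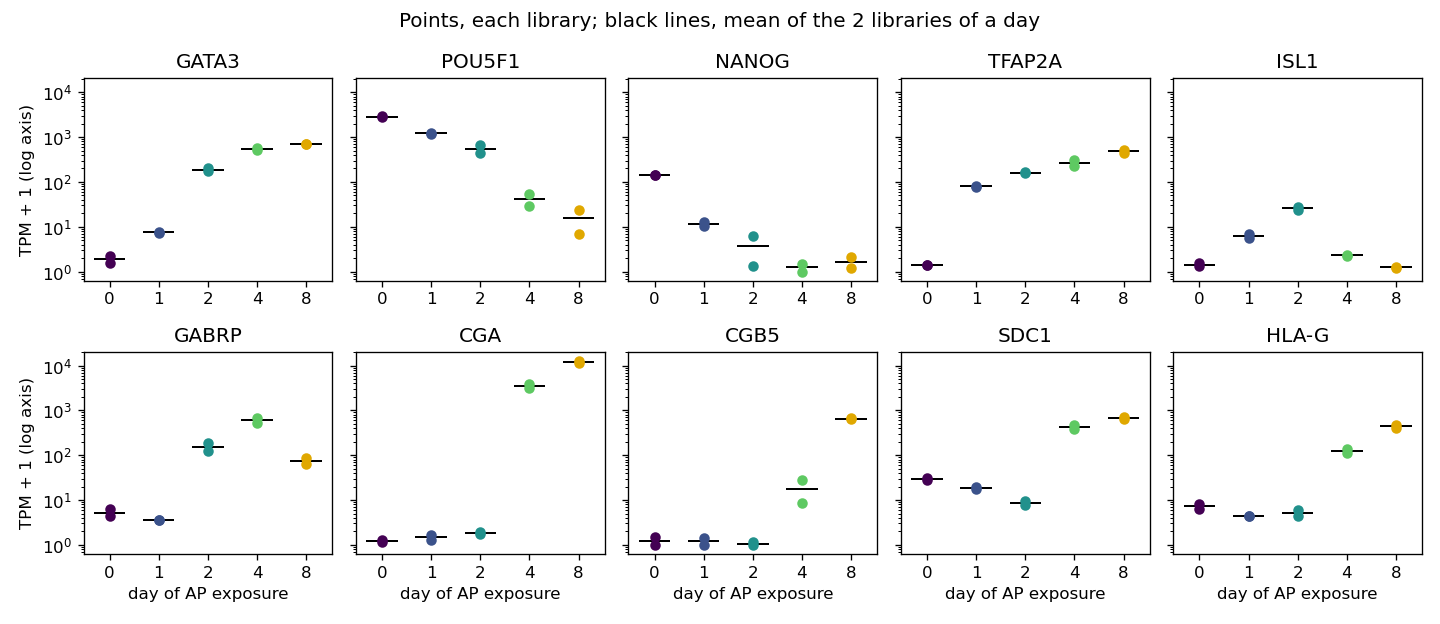
TPM + 1 on a log axis (y) against the day of exposure (x) for GATA3, POU5F1, NANOG, TFAP2A, ISL1, GABRP, CGA, CGB5, SDC1 and HLA-G, with points for single libraries (n = 2 per day) and lines through the means. POU5F1 runs from 2855 TPM at day 0 to 14.4 at day 8, and CGA from 0.225 to 12036.

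The comparison of day 1 with day 0 asked what differed after the first day of exposure, with no unexposed cells of the same age to compare. Genes of the Nodal pathway were among the strongest decreases. LEFTY1, a Nodal antagonist induced by Nodal itself, fell from 137 ± 89.0 to 0.270 ± 0.382 TPM (log2 change -6.62 ± 0.46, limma adjusted p = 8.56e-05, and -5.91 without day 0 replicate 1 and -7.34 without day 0 replicate 2). NODAL, the ligand, fell from 46.1 ± 9.38 to 1.30 ± 0.778 TPM (log2 change -4.38 ± 0.38, limma adjusted p = 2.54e-04). DUSP6, a phosphatase induced by ERK signalling, fell from 42.8 ± 12.8 to 2.08 ± 0.417 TPM (log2 change -3.80 ± 0.21, limma adjusted p = 3.00e-05). In the other direction TFAP2A rose from 0.415 to 78.4 TPM (log2 change 5.81 ± 0.14). HAND1, a basic helix-loop-helix factor of trophoblast and extraembryonic mesoderm, rose from 0.575 to 60.3 TPM (log2 change 5.32 ± 0.20), and ID2, a direct target of BMP signalling, rose from 16.1 to 217 TPM (log2 change 3.69 ± 0.15). In all 1877 genes were higher and 1771 lower at day 1.

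Of the 8 tested Activin and Nodal targets, 7 fell and 1 did not pass, and 7 fell when adjusted over the list alone (camera adjusted p = 1.24e-07, adjusted p = 0.334 with an estimated correlation). CER1, a secreted antagonist, fell from 62.9 ± 43.1 to 1.00 ± 1.01 TPM (log2 change -4.91 ± 0.51, limma adjusted p = 6.16e-04, and -4.16 without day 0 replicate 1 and -5.66 without day 0 replicate 2). LEFTY2 fell from 137 ± 149 to 2.10 ± 0.771 TPM (log2 change -4.88 ± 0.74, limma adjusted p = 0.00339, and -3.44 without day 0 replicate 1 and -6.32 without day 0 replicate 2). Reads of LEFTY1 and LEFTY2, which are near-identical in part, can be shared. Among 18 FGF and ERK targets, 16 fell and 2 did not pass, and 1 rose and 16 fell when adjusted over the list alone (camera adjusted p = 8.16e-11, adjusted p = 0.334 with an estimated correlation). MYC, a growth regulator, fell from 80.3 to 12.3 TPM (log2 change -2.69 ± 0.26) and SPRY4, a feedback inhibitor of the pathway, from 47.9 to 6.78 TPM (log2 change -2.64 ± 0.25). ETV1, an ETS factor, fell from 30.5 to 5.07 TPM (log2 change -2.38 ± 0.18). Of the 9 tested BMP targets, 5 rose, 1 fell and 3 did not pass, and 5 rose and 1 fell when adjusted over the list alone (camera adjusted p = 3.80e-04, adjusted p = 0.126 with an estimated correlation). SMAD6, an inhibitor of BMP signalling, rose from 1.50 to 27.8 TPM (log2 change 3.60 ± 0.28) and ID1 from 137 to 674 TPM (log2 change 2.32 ± 0.16). SMAD7, an inhibitor shared with the Activin branch, fell from 22.1 to 11.4 TPM (log2 change -0.89 ± 0.14).

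Of 16 early ectoderm and trophoblast factors, 12 rose and 4 did not pass, and 12 rose when adjusted over the list alone (camera adjusted p = 1.44e-13, adjusted p = 0.0554 with an estimated correlation). DLX5 and DLX3, homeobox factors, rose from 0.0450 to 22.4 TPM (log2 change 4.48 ± 0.11) and from 0.130 to 18.1 TPM (log2 change 4.08 ± 0.16). Of the 21 pluripotency genes, 2 rose, 10 fell and 9 did not pass, and 2 rose and 12 fell when adjusted over the list alone (camera adjusted p = 7.21e-04, adjusted p = 0.652 with an estimated correlation). FOXD3, a forkhead factor, fell from 17.0 to 2.02 TPM (log2 change -2.57 ± 0.20) and GDF3, a TGF-beta family ligand, from 20.5 to 2.90 TPM (log2 change -2.45 ± 0.21). In contrast LIN28A, an RNA-binding protein, rose from 535 to 1055 TPM (log2 change 0.98 ± 0.07). Of the 14 epithelial junction genes, 5 rose, 2 fell and 7 did not pass, and 6 rose and 3 fell when adjusted over the list alone (camera adjusted p = 0.0175, adjusted p = 0.567 with an estimated correlation). CLDN4, a claudin of tight junctions, rose from 10.8 to 127 TPM (log2 change 3.47 ± 0.15). Among p53 targets and arrest genes, 4 rose and 8 did not pass, and 6 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.0104, adjusted p = 0.334 with an estimated correlation). CDKN1C, an imprinted inhibitor of cyclin-dependent kinases, rose from 8.54 to 84.2 TPM (log2 change 3.16 ± 0.14). Of the 12 glycolysis genes, 1 rose, 5 fell and 6 did not pass, and 2 rose and 6 fell when adjusted over the list alone (camera adjusted p = 0.0292, adjusted p = 0.575 with an estimated correlation). LDHA, lactate dehydrogenase, fell from 524 to 209.7 TPM (log2 change -1.30 ± 0.19) and SLC2A1, a glucose transporter, from 212 to 88.7 TPM (log2 change -1.25 ± 0.09). Of 12 stress response genes, 4 fell and 8 did not pass, and 4 fell when adjusted over the list alone (camera adjusted p = 0.0103, adjusted p = 0.334 with an estimated correlation). TRIB3, a pseudokinase of the integrated stress response, fell from 18.9 to 4.50 TPM (log2 change -1.86 ± 0.23).

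Outside these lists, LHX5, a LIM homeobox factor, rose from 0.210 to 32.2 TPM (log2 change 4.77 ± 0.19) and UPK2, a uroplakin of urothelium, from 0.160 to 25.4 TPM (log2 change 4.51 ± 0.15). EDNRB, an endothelin receptor, fell from 41.3 to 3.04 TPM (log2 change -3.36 ± 0.22). The counts of this step rest on few libraries. Leaving out day 1 replicate 2 left 825 higher and 514 lower genes, leaving out day 1 replicate 1 left 1174 and 1159, and leaving out day 0 replicate 2 left 1063 lower. A fit to the libraries of days 0 and 1 alone called 538 higher and 314 lower and lost the junction (adjusted p = 0.0914) and glycolysis (0.114) lists. The junction list was also lost without day 0 replicate 1 (camera adjusted p = 0.0610). The lowest adjusted p over 22 alternatives was 0.00132 for the junction list and 0.00812 for glycolysis.

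Day 2 was set against day 1 to follow the step at which GATA3 rose from 6.50 to 189 TPM. EPAS1, a hypoxia-inducible transcription factor, rose from 2.96 ± 0.403 to 344 ± 80.0 TPM (log2 change 6.43 ± 0.15, limma adjusted p = 7.08e-07). WLS, a carrier needed for WNT secretion, rose from 5.65 ± 3.90 to 427 ± 37.1 TPM (log2 change 6.14 ± 0.33, limma adjusted p = 1.33e-05, and 6.78 without day 1 replicate 1 and 5.51 without day 1 replicate 2). KRT7 rose from 22.3 to 680.3 TPM (log2 change 4.88 ± 0.12) and GABRP from 2.65 to 155 TPM (log2 change 5.39 ± 0.25). H19, an imprinted non-coding RNA of the placenta, rose from 8.59 to 439 TPM (log2 change 5.46 ± 0.25). SOX2 fell from 154 to 25.4 TPM (log2 change -2.57 ± 0.21). PPP1R1B, a regulator of protein phosphatase 1, fell from 108 ± 22.5 to 2.12 ± 1.14 TPM (log2 change -5.16 ± 0.36, limma adjusted p = 4.40e-05). In all 2445 genes were higher and 2431 lower at day 2, and after median-of-ratios scaling 2161 were higher and 2652 lower.

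Of the 12 amnion markers, 10 rose and 2 did not pass, and 10 rose when adjusted over the list alone (camera adjusted p = 1.16e-10, adjusted p = 0.0629 with an estimated correlation). CTSV, a cathepsin, rose from 94.6 to 1781 TPM (log2 change 4.22 ± 0.13) and WNT6, a WNT ligand, from 1.09 to 58.7 TPM (log2 change 4.83 ± 0.15). VTCN1, a B7 family protein, rose from 0.275 to 33.9 TPM (log2 change 4.73 ± 0.26). Among the 16 early ectoderm and trophoblast factors, 15 rose and 1 did not pass, and 15 rose and 1 fell when adjusted over the list alone (camera adjusted p = 4.11e-13, adjusted p = 0.0598 with an estimated correlation). TBX3, a T-box factor, rose from 0.515 to 61.0 TPM (log2 change 5.36 ± 0.16) and MSX2, a homeobox factor, from 7.90 to 134 TPM (log2 change 3.92 ± 0.12). Of 8 keratins tested among 12 listed, 7 rose and 1 did not pass, and 7 rose when adjusted over the list alone (camera adjusted p = 5.19e-08, adjusted p = 0.0629 with an estimated correlation). KRT23 and KRT80 were under 1 TPM in every library of days 0 and 1 and passed the level filter only through later days. KRT80 rose from 0.795 to 6.61 TPM (log2 change 2.09 ± 0.14) and KRT8 from 942 to 4328 TPM (log2 change 2.20 ± 0.11). For 16 cytotrophoblast markers, 9 rose, 1 fell and 6 did not pass, and 9 rose and 1 fell when adjusted over the list alone (camera adjusted p = 6.44e-05, adjusted p = 0.103 with an estimated correlation). VGLL1, a cofactor of TEAD proteins, rose from 2.56 to 91.2 TPM (log2 change 4.70 ± 0.20) and LRP2, an endocytic receptor, from 4.36 to 52.1 TPM (log2 change 3.33 ± 0.25). Against the list ITGA6, a laminin-binding integrin, fell from 52.7 to 30.4 TPM (log2 change -0.78 ± 0.14). Of the 14 epithelial junction genes, 8 rose, 1 fell and 5 did not pass, and 9 rose and 1 fell when adjusted over the list alone (camera adjusted p = 2.65e-05, adjusted p = 0.202 with an estimated correlation). TACSTD2, a surface glycoprotein of trophoblast, rose from 25.1 to 169.9 TPM (log2 change 2.71 ± 0.17) and DSP, a desmosomal plakin, from 30.0 to 135 TPM (log2 change 2.13 ± 0.13). Of the 39 listed HOX genes 5 were tested, and 5 rose, and 5 rose when adjusted over the list alone (camera adjusted p = 6.70e-05, adjusted p = 0.0629 with an estimated correlation). HOXB2 rose from 0.0750 to 25.5 TPM (log2 change 4.60 ± 0.31). All 5 were under 1 TPM in every library of days 0 and 1, so they passed the level filter only through later days, and their count and list call are no independent evidence of a rise.

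Of the 21 pluripotency genes, 19 fell and 2 did not pass, and 19 fell when adjusted over the list alone (camera adjusted p = 6.46e-12, adjusted p = 0.268 with an estimated correlation). UTF1, a chromatin factor of stem cells, fell from 6.71 to 0.255 TPM (log2 change -2.62 ± 0.22) and ZIC3, a zinc-finger factor, from 195 to 38.5 TPM (log2 change -2.44 ± 0.39, and -3.07 without day 2 replicate 1 and -1.81 without day 2 replicate 2). Of 17 cholesterol synthesis genes, 7 rose and 10 did not pass, and 7 rose when adjusted over the list alone (camera adjusted p = 9.23e-04, adjusted p = 0.530 with an estimated correlation). DHCR24, a sterol reductase, rose from 126 to 177 TPM (log2 change 0.50 ± 0.07). For the 13 mitochondrially encoded mRNAs, 3 fell and 10 did not pass, and 3 fell when adjusted over the list alone (camera adjusted p = 0.00797, adjusted p = 0.690 with an estimated correlation). Mitochondrial transcripts took 7.50 ± 0.700% of TPM at day 1 and 5.74 ± 1.21% at day 2 (SD, n = 2). That list was lost without day 1 replicate 2 (camera adjusted p = 0.0763), without day 2 replicate 1 (0.231) and by fry (0.183), and its lowest over 21 alternatives was 2.42e-06. Without day 1 replicate 2 the counts were 1485 higher and 1317 lower, without day 2 replicate 2 they were 1578 and 1334, and without day 1 replicate 1 1455 genes were lower.

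From day 2 to day 4, 29 of the 38 tested syncytiotrophoblast genes rose. CGA rose from 0.865 ± 0.106 to 3509.7 ± 533 TPM (log2 change 10.87 ± 0.15, limma adjusted p = 8.63e-09). HSD3B1, the placental enzyme that makes progesterone, rose from 0.760 ± 0.354 to 531 ± 25.2 TPM (log2 change 8.25 ± 0.14, limma adjusted p = 1.41e-08). CYP19A1, the aromatase that makes oestrogens, rose from 1.23 to 529 TPM (log2 change 7.89 ± 0.23). POU5F1 fell from 557 to 41.0 TPM (log2 change -3.77 ± 0.52) and SOX2 from 25.4 to 0.690 TPM (log2 change -3.95 ± 0.21). The amnion factor ISL1 fell from 24.8 to 1.32 TPM (log2 change -3.47 ± 0.17). In all 3632 genes were higher and 4293 lower at day 4, so 45.8% of the calls were higher. The majority turned after median-of-ratios scaling, with 4006 higher and 3583 lower (52.8% higher), without day 2 replicate 1, with 2877 higher and 2740 lower, and with an absolute log2 change of at least 1, with 1739 higher and 1240 lower.

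Of the 38 tested syncytiotrophoblast genes, 29 rose and 9 did not pass, and 29 rose when adjusted over the list alone (camera adjusted p = 1.88e-20, adjusted p = 0.105 with an estimated correlation). Of the 38, 18 were under 1 TPM in every library of days 0 to 2 and passed the level filter only through days 4 and 8, while 1 of the 39 listed genes was not tested. The retroviral envelope genes ERVW-1, ERVV-1 and ERVV-2 rose from 0.335 to 359 TPM (log2 change 8.06 ± 0.20), from 0.480 to 412 TPM (log2 change 8.13 ± 0.14) and from 0.105 to 364 TPM (log2 change 8.36 ± 0.15). Reads of ERVV-1 and ERVV-2 can be shared between both copies. HOPX, a homeodomain protein without DNA binding, rose from 1.06 to 549 TPM (log2 change 8.06 ± 0.15). Of the 12 extravillous trophoblast markers tested among 16 listed, 8 rose and 4 did not pass, and 8 rose when adjusted over the list alone (camera adjusted p = 0.00197, adjusted p = 0.327 with an estimated correlation). HTRA4 and MMP12 were under 1 TPM in every library of days 0 to 2 and passed the level filter only through days 4 and 8. MMP2, a gelatinase, rose from 14.2 to 645 TPM (log2 change 5.55 ± 0.36, and 6.23 without day 2 replicate 1 and 4.87 without day 2 replicate 2) and HTRA4, a serine protease of placenta, from 0.300 to 11.7 TPM (log2 change 3.29 ± 0.16). Of 8 keratins, 4 rose and 4 did not pass, and 4 rose when adjusted over the list alone (camera adjusted p = 0.00351, adjusted p = 0.327 with an estimated correlation). KRT23 rose from 1.88 to 294 TPM (log2 change 6.74 ± 0.24) and KRT17 from 6.58 to 86.3 TPM (log2 change 3.47 ± 0.36). Of 14 interferon-stimulated genes, 12 rose and 2 did not pass, and 12 rose when adjusted over the list alone (camera adjusted p = 3.96e-08, adjusted p = 0.197 with an estimated correlation). MX1, an antiviral GTPase, rose from 1.74 to 76.2 TPM (log2 change 4.85 ± 0.23), IFI6 from 13.8 to 249 TPM (log2 change 4.09 ± 0.15). OAS1, an oligoadenylate synthetase, rose from 0.350 to 14.3 TPM (log2 change 3.51 ± 0.16).

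Of the 21 pluripotency genes, 14 fell and 7 did not pass, and 14 fell when adjusted over the list alone (camera adjusted p = 8.04e-05, adjusted p = 0.477 with an estimated correlation). VRTN, a stem-cell transcription factor, fell from 19.4 to 0.390 TPM (log2 change -3.71 ± 0.44, and -2.94 without day 2 replicate 1 and -4.48 without day 2 replicate 2). Of 23 proliferation genes, 1 rose, 16 fell and 6 did not pass, and 1 rose and 16 fell when adjusted over the list alone (camera adjusted p = 4.52e-06, adjusted p = 0.327 with an estimated correlation). MCM3 and MCM2, parts of the replicative helicase, fell from 210.1 to 106 TPM (log2 change -0.99 ± 0.08) and from 102 to 51.5 TPM (log2 change -0.97 ± 0.07). Members of lists that were not called moved both ways. GATA2, a partner of GATA3 in trophoblast, rose from 59.0 to 621 TPM (log2 change 3.38 ± 0.16) while CDX2 fell from 11.3 to 0.315 TPM (log2 change -3.23 ± 0.28). CLDN10, a claudin, fell from 130.2 to 8.57 TPM (log2 change -3.75 ± 0.17) while IGFBP5, an IGF-binding protein, rose from 11.5 to 124 TPM (log2 change 3.36 ± 0.34). ID1 fell from 714 to 84.4 TPM (log2 change -3.07 ± 0.16) while SMAD7 rose from 16.6 to 80.4 TPM (log2 change 2.22 ± 0.14). Of 18 mesenchyme and fibroblast genes, 8 rose, 3 fell and 7 did not pass, and 8 rose and 3 fell when adjusted over the list alone (camera adjusted p = 0.0886, adjusted p = 0.751 with an estimated correlation). LUM, the matrix proteoglycan lumican, rose from 1.49 to 169 TPM (log2 change 6.16 ± 0.33) and COL6A1, a collagen VI chain, fell from 55.2 to 15.4 TPM (log2 change -1.78 ± 0.14). Of the 17 cholesterol synthesis genes, 8 rose, 2 fell and 7 did not pass, and 9 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.0488, adjusted p = 0.751 with an estimated correlation). SQLE, squalene epoxidase, rose from 111 to 203 TPM (log2 change 0.85 ± 0.12) and SC5D, a sterol desaturase, fell from 195 to 115 TPM (log2 change -0.76 ± 0.09). That last list was lost by fry (0.0614), with a mean TPM of at least 5 (0.0670), after quantile normalization (0.160) and without day 2 replicate 1 (0.0607), day 4 replicate 2 (0.0955), day 8 replicate 1 (0.0551) or day 8 replicate 2 (0.0552), and its lowest over 22 alternatives was 0.00815. Without day 2 replicate 1, 2740 genes were lower.

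Between day 4 and day 8, 32 of 38 syncytiotrophoblast genes rose and 8 of 12 amnion markers fell. CGB3, a beta subunit gene of chorionic gonadotropin, rose from 20.4 ± 6.71 to 782 ± 24.9 TPM (log2 change 5.23 ± 0.20, limma adjusted p = 3.27e-06). PSG4, a pregnancy-specific glycoprotein, rose from 0.825 to 25.4 TPM (log2 change 3.89 ± 0.27) and TREML2, a receptor-like surface protein, from 14.2 to 401 TPM (log2 change 4.73 ± 0.13). GABRP fell from 611 to 74.0 TPM (log2 change -3.03 ± 0.25) and H19 from 4160.5 ± 748 to 90.6 ± 0.530 TPM (log2 change -5.49 ± 0.25, limma adjusted p = 6.46e-06). In all 3529 genes were higher and 5010 lower at day 8, so 41.3% of the calls were higher. After median-of-ratios scaling 4652 were higher and 3649 lower (56.0% higher), and the median log2 change of all tested genes moved from -0.11 to 0.01.

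Among 38 syncytiotrophoblast genes, 32 rose, 1 fell and 5 did not pass, and 32 rose and 1 fell when adjusted over the list alone (camera adjusted p = 4.08e-14, adjusted p = 0.231 with an estimated correlation). CGB5 and CGB8 rose from 17.1 to 650.1 TPM (log2 change 5.41 ± 0.48, and 4.55 without day 4 replicate 1 and 6.26 without day 4 replicate 2) and from 19.6 to 776 TPM (log2 change 5.30 ± 0.30). Reads of CGB3, CGB5 and CGB8 can be shared between these near-identical copies. CRH, corticotropin-releasing hormone, fell from 10.8 to 0.325 TPM (log2 change -3.12 ± 0.28). Of the 10 listed pregnancy-specific glycoproteins, which also share reads, 6 were tested, and 6 rose, and 6 rose when adjusted over the list alone (camera adjusted p = 6.09e-05, adjusted p = 0.312 with an estimated correlation). All 6 were under 1 TPM in every library of days 0 to 2, so they passed the level filter only through days 4 and 8. Their mean log2 change from day 0 was 0.21 and 0.80 in the day 4 libraries and 3.59 and 3.35 in those of day 8. The filter thus leaned on day 8, and their count and list call are no independent evidence of a rise. Of the 12 extravillous trophoblast markers, 7 rose and 5 did not pass, and 7 rose when adjusted over the list alone (camera adjusted p = 0.0140, adjusted p = 0.394 with an estimated correlation). HLA-G rose from 122 to 439.9 TPM (log2 change 1.85 ± 0.19) and MMP12, a macrophage elastase, from 0.590 to 11.2 TPM (log2 change 2.94 ± 0.17). MMP12 could not have passed the level filter without day 8, so its rise is no independent evidence. Of 8 endothelium and blood genes tested among 12 listed, 5 rose and 3 did not pass, and 5 rose when adjusted over the list alone (camera adjusted p = 0.0206, adjusted p = 0.313 with an estimated correlation). CDH5 and PECAM1 were under 1 TPM in every library of days 0 to 2 and passed the level filter only through days 4 and 8. CDH5, VE-cadherin, rose from 55.4 to 263 TPM (log2 change 2.25 ± 0.19). Of the 11 tested naive-state genes, 5 rose, 1 fell and 5 did not pass, and 5 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.0198, adjusted p = 0.313 with an estimated correlation). DPPA3, an oocyte and germ-cell factor, rose from 3.81 to 27.7 TPM (log2 change 2.58 ± 0.17) and TFCP2L1, a grainyhead-family factor, from 14.7 to 53.5 TPM (log2 change 1.80 ± 0.16). SUSD2, a surface protein of naive cells, fell from 28.4 to 10.8 TPM (log2 change -1.31 ± 0.19). Of the 13 mitochondrially encoded mRNAs, 4 rose and 9 did not pass, and 3 rose when adjusted over the list alone (camera adjusted p = 0.0341, adjusted p = 0.670 with an estimated correlation). Mitochondrial transcripts took 4.65 ± 0.420% of TPM at day 4 and 6.32 ± 0.416% at day 8 (SD, n = 2).

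Of the 12 amnion markers, 2 rose, 8 fell and 2 did not pass, and 2 rose and 8 fell when adjusted over the list alone (camera adjusted p = 0.0341, adjusted p = 0.403 with an estimated correlation). VTCN1 fell from 137 to 27.9 TPM (log2 change -2.25 ± 0.26) and IGFBP3, an IGF-binding protein, from 853 to 196 TPM (log2 change -2.11 ± 0.16). Of the 5 HOX genes, 4 fell and 1 did not pass, and 5 fell when adjusted over the list alone (camera adjusted p = 0.0341, adjusted p = 0.313 with an estimated correlation). HOXB2 fell from 20.1 to 2.80 TPM (log2 change -2.53 ± 0.31). Of the 23 proliferation genes, 4 rose, 17 fell and 2 did not pass, and 4 rose and 17 fell when adjusted over the list alone (camera adjusted p = 0.00126, adjusted p = 0.375 with an estimated correlation). AURKB, a kinase of the chromosomal passenger complex, fell from 78.1 to 24.7 TPM (log2 change -1.62 ± 0.07) and MKI67 from 40.6 to 16.2 TPM (log2 change -1.26 ± 0.15). In contrast CCNB1, cyclin B1, rose from 382 to 1408 TPM (log2 change 1.88 ± 0.06) and RRM2, a ribonucleotide reductase subunit, from 222 to 477 TPM (log2 change 1.10 ± 0.14). Of 12 glycolysis genes, 1 rose, 10 fell and 1 did not pass, and 1 rose and 10 fell when adjusted over the list alone (camera adjusted p = 0.0104, adjusted p = 0.403 with an estimated correlation). GAPDH fell from 3960.5 to 1888 TPM (log2 change -1.07 ± 0.06) and SLC2A1 rose from 649 to 1032 TPM (log2 change 0.67 ± 0.09). Of the 12 imprinted genes, 1 rose, 6 fell and 5 did not pass, and 1 rose and 6 fell when adjusted over the list alone (camera adjusted p = 0.0473, adjusted p = 0.313 with an estimated correlation). PEG10, a retrotransposon-derived placental gene, fell from 460.0 to 63.0 TPM (log2 change -2.85 ± 0.18) and MEG3, a non-coding RNA, rose from 14.6 to 32.0 TPM (log2 change 1.14 ± 0.23). HAND1 fell from 178 to 15.4 TPM (log2 change -3.44 ± 0.20) and PLP1, a myelin protein, from 103 to 1.81 TPM (log2 change -5.23 ± 0.17).

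With a mean TPM of at least 5, camera no longer called the naive-state (adjusted p = 0.0817), amnion (0.0533), extravillous (0.0833), endothelium (0.118), glycolysis (0.0533), imprinted (0.0833) and mitochondrial (0.0565) lists. The HOX list ended with a pseudocount of 0.1 (0.120), with no filter (0.239) and without day 4 replicate 2 (0.0515). The amnion list ended without day 4 replicate 2 (0.0766). The mitochondrial list ended by fry (0.198), after quantile normalization (0.109) and without day 4 replicate 1 (0.158) or day 8 replicate 1 (0.107). The imprinted list ended with a pseudocount of 0.1 (0.0508) and without day 1 replicate 1 (0.0530), day 1 replicate 2 (0.0530), day 4 replicate 1 (0.0675), day 4 replicate 2 (0.0913) or day 8 replicate 1 (0.0576). The lowest adjusted p over the alternatives was 3.17e-04 for the amnion, 0.0153 for the mitochondrial, and 2.42e-05 for the HOX and imprinted lists, 2.41e-04 for naive-state, 3.32e-04 for extravillous, 3.17e-04 for endothelium and 1.75e-04 for glycolysis genes.

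Day 8 against day 0 gave the whole change of the series. CGA rose from 0.225 ± 0.120 to 12036 ± 1019.6 TPM (log2 change 13.26 ± 0.15, limma adjusted p = 1.79e-09), CYP19A1 from 0.565 to 1733 TPM (log2 change 10.16 ± 0.23) and HOPX from 0.240 to 1411 TPM (log2 change 10.17 ± 0.15). HSD3B1 was listed at 0 in both day 0 libraries and stood at 1955 ± 24.2 TPM at day 8. S100P, a calcium-binding protein, was likewise listed at 0 and reached 1000.4 ± 16.6 TPM. GATA2, DLX3 and MSX2 rose from 0.660 to 761 TPM (log2 change 8.86 ± 0.16), from 0.130 to 444 TPM (log2 change 8.63 ± 0.16) and from 1.25 to 759 TPM (log2 change 8.40 ± 0.12). POU5F1 fell from 2855 ± 57.7 to 14.4 ± 11.96 TPM (log2 change -7.80 ± 0.52, limma adjusted p = 2.88e-06, and -6.91 without day 8 replicate 1 and -8.69 without day 8 replicate 2). PRDM14, a repressor of differentiation genes, fell from 138 to 0.460 TPM (log2 change -6.58 ± 0.24). In all 5420 genes were higher and 7767 lower at day 8. The median log2 change over all tested genes was -0.25, or -0.06 after median-of-ratios scaling. List medians are given beside that shift.

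Of the 38 syncytiotrophoblast genes, 35 rose, 1 fell and 2 did not pass, and 35 rose and 2 fell when adjusted over the list alone (camera adjusted p = 1.59e-16, adjusted p = 0.0831 with an estimated correlation). Their median log2 change was 7.16, and the same 18 genes passed the level filter only through days 4 and 8. TFPI2, a protease inhibitor, was the member that fell, from 40.7 to 5.21 TPM (log2 change -2.73 ± 0.32). Of the 6 pregnancy-specific glycoproteins, 6 rose, and 6 rose when adjusted over the list alone (camera adjusted p = 0.00107, adjusted p = 0.247 with an estimated correlation), which is no independent evidence of a rise, since the level filter kept them only through days 4 and 8. PSG5, PSG6 and PSG9 were listed at 0 in both day 0 libraries. Of the 12 extravillous trophoblast markers, 10 rose and 2 fell, and 10 rose and 2 fell when adjusted over the list alone (camera adjusted p = 4.91e-04, adjusted p = 0.247 with an estimated correlation). HTRA4 and MMP12 passed the level filter only through days 4 and 8, and 4 of the 16 listed markers were not tested. HLA-G rose from 6.36 to 439.9 TPM (log2 change 5.91 ± 0.19) and DIO2, a deiodinase, from 0.365 to 29.1 TPM (log2 change 4.48 ± 0.20). Of the 12 amnion markers, 8 rose, 2 fell and 2 did not pass, and 8 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.00419, adjusted p = 0.279 with an estimated correlation). HEY1, a Notch target, rose from 0.720 to 57.3 TPM (log2 change 5.09 ± 0.29) and CLDN10 fell from 12.4 to 2.84 TPM (log2 change -1.80 ± 0.17). Of the 16 early ectoderm and trophoblast factors, 14 rose and 2 did not pass, and 14 rose when adjusted over the list alone (camera adjusted p = 6.47e-09, adjusted p = 0.0831 with an estimated correlation). Their median was 4.77. Of the 8 keratins, 7 rose and 1 did not pass, and 7 rose and 1 fell when adjusted over the list alone (camera adjusted p = 1.29e-04, adjusted p = 0.204 with an estimated correlation). KRT7 rose from 14.3 to 534 TPM (log2 change 5.13 ± 0.12), and KRT23, listed at 0 at day 0, reached 749 ± 52.8 TPM. KRT23 and KRT80 passed the level filter only through days after day 1, and 4 of the 12 listed keratins were not tested. Of the 21 pluripotency genes, 21 fell, and 21 fell when adjusted over the list alone (camera adjusted p = 4.50e-08, adjusted p = 0.303 with an estimated correlation), and their median was -4.25.

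Of the 14 interferon-stimulated genes, 13 rose and 1 did not pass, and 13 rose when adjusted over the list alone (camera adjusted p = 3.04e-06, adjusted p = 0.204 with an estimated correlation). IFI6 rose from 6.59 to 566 TPM (log2 change 6.23 ± 0.15) and IFI27 from 0.870 to 13.1 TPM (log2 change 2.93 ± 0.31). Of 12 p53 targets and arrest genes, 8 rose, 2 fell and 2 did not pass, and 8 rose and 3 fell when adjusted over the list alone (camera adjusted p = 0.0135, adjusted p = 0.279 with an estimated correlation). CDKN1C rose from 8.54 to 742 TPM (log2 change 6.28 ± 0.14) and GDF15, a stress-induced cytokine, from 19.9 to 349.5 TPM (log2 change 4.11 ± 0.22). CDKN1A, the p21 inhibitor, rose from 22.5 to 149.6 TPM (log2 change 2.72 ± 0.20). Against the list BBC3, a pro-apoptotic BCL2 family member, fell from 23.5 to 10.5 TPM (log2 change -1.09 ± 0.17). Of the 23 proliferation genes, 4 rose and 19 fell, and 4 rose and 19 fell when adjusted over the list alone (camera adjusted p = 5.33e-04, adjusted p = 0.279 with an estimated correlation). BUB1, a checkpoint kinase, fell from 109 to 23.7 TPM (log2 change -2.15 ± 0.08) and CCNB1 rose from 350.4 to 1408 TPM (log2 change 2.00 ± 0.06). Of the 11 tested naive-state genes, 7 rose, 2 fell and 2 did not pass, and 7 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.0376, adjusted p = 0.247 with an estimated correlation). KLF4, a zinc-finger factor also of epithelia, rose from 3.98 to 195 TPM (log2 change 5.31 ± 0.17) and DPPA2 fell from 9.02 to 0.975 TPM (log2 change -2.33 ± 0.21). The naive-state list was lost after median-of-ratios scaling (camera adjusted p = 0.0634) and without day 8 replicate 2 (0.0643), with a lowest p of 6.70e-06 over 22 alternatives.

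**Figure D3:**
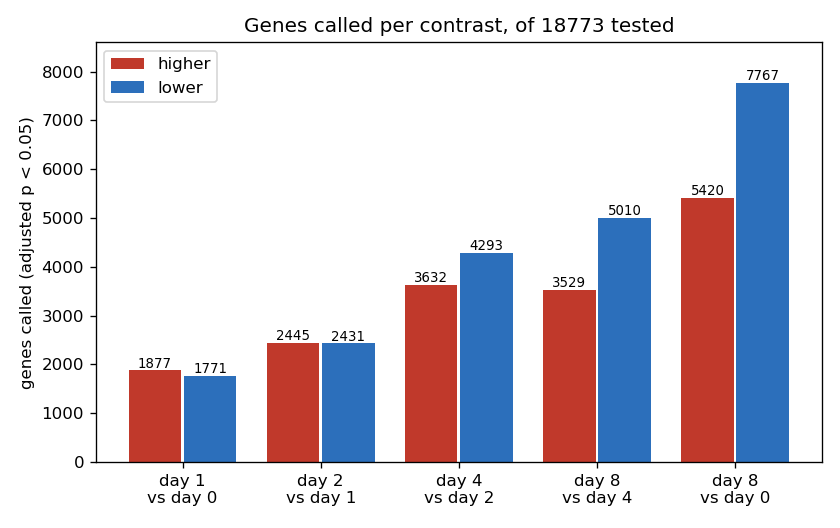
Number of genes with limma adjusted p under 0.05 (y axis, from 0) that were higher or lower in the later day of each of the 5 comparisons (x axis). Day 8 against day 0 has 5420 higher and 7767 lower, day 1 against day 0 has 1877 and 1771.

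**Figure D4:**
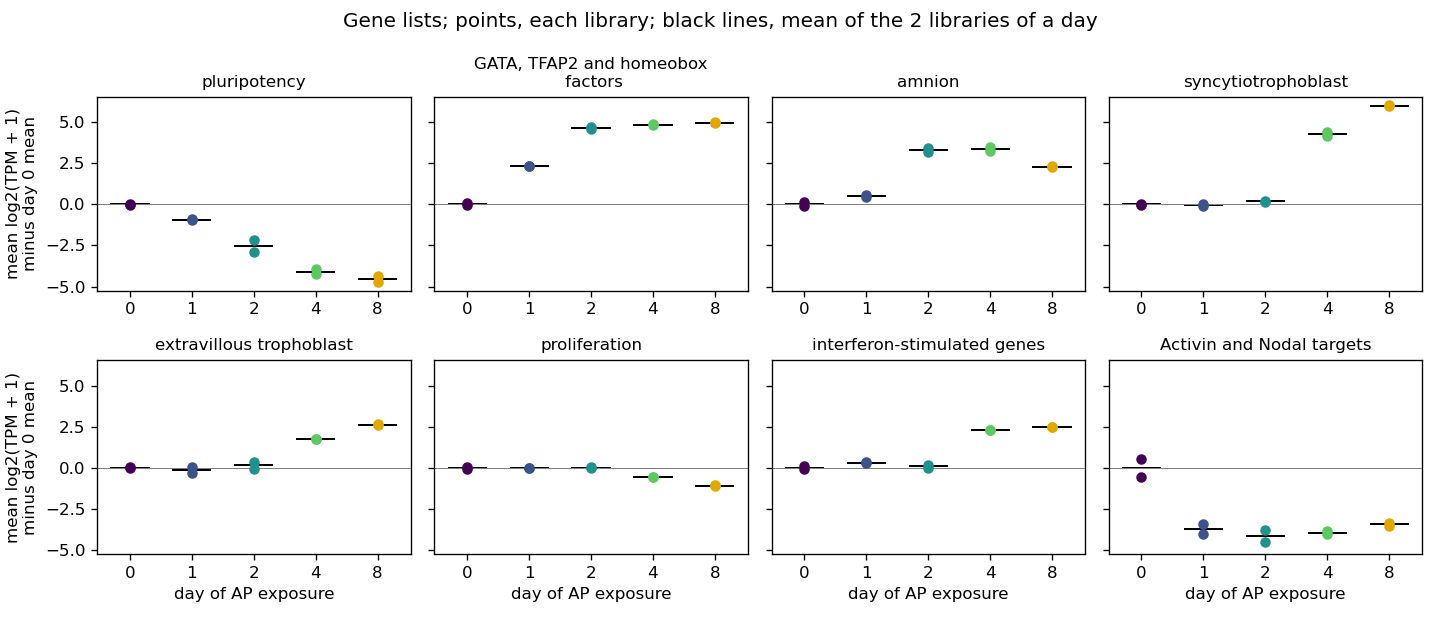
Mean log2(TPM + 1) over the members of 8 gene lists minus its day 0 mean (y axis) against the day of exposure (x axis), with points for single libraries (n = 2 per day) and lines through the day means. At day 8 the plotted means of both libraries were 5.98 and 6.01 for syncytiotrophoblast genes and -4.70 and -4.35 for pluripotency genes. The panel titled GATA, TFAP2 and homeobox factors also holds HAND1, TBX3 and grainyhead genes.

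Lists of other cell types and pathways, which camera called in none of the comparisons or not in this one, were read at day 8 against day 0. Of the 4 tested mesoderm markers, 4 fell, and 4 fell when adjusted over the list alone (camera adjusted p = 0.126, adjusted p = 0.311 with an estimated correlation). KDR, a VEGF receptor, fell from 20.5 to 2.97 TPM (log2 change -2.43 ± 0.24). The other 11 of 15 listed mesoderm genes were not tested. Of the 7 tested endoderm markers, 4 rose, 2 fell and 1 did not pass, and 4 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.116, adjusted p = 0.483 with an estimated correlation). The other 5 of 12 listed endoderm genes were not tested. Of the 7, 2 were under 1 TPM in every library of days 0 to 2 and passed the level filter only through later days. GATA6, a zinc-finger factor, rose from 0.525 to 24.7 TPM (log2 change 4.11 ± 0.21) and AFP, alpha-fetoprotein, fell from 51.1 to 4.93 TPM (log2 change -3.22 ± 0.75). Of the 3 tested neuroectoderm markers, 3 fell, and 3 fell when adjusted over the list alone (camera adjusted p = 0.0740, adjusted p = 0.341 with an estimated correlation). OTX2, a homeobox factor, fell from 33.1 to 0.880 TPM (log2 change -4.19 ± 0.28). The other 9 of 12 listed neuroectoderm genes were not tested. Of the 7 tested neural crest markers, 3 rose and 4 fell, and 3 rose and 4 fell when adjusted over the list alone (camera adjusted p = 0.887, adjusted p = 0.891 with an estimated correlation). SOX9 rose from 1.44 to 12.3 TPM (log2 change 2.45 ± 0.16) and ETS1 fell from 42.0 to 3.25 TPM (log2 change -3.34 ± 0.13). Of the 18 mesenchyme and fibroblast genes, 5 rose, 10 fell and 3 did not pass, and 6 rose and 10 fell when adjusted over the list alone (camera adjusted p = 0.556, adjusted p = 0.891 with an estimated correlation). THY1, a surface glycoprotein of fibroblasts and stem cells, fell from 379 to 3.86 TPM (log2 change -6.26 ± 0.50). Of the 8 WNT targets, 4 rose, 2 fell and 2 did not pass, and 4 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.410, adjusted p = 0.610 with an estimated correlation). TCF7, a WNT effector, fell from 19.8 to 1.93 TPM (log2 change -2.75 ± 0.36). Of the 11 MHC class I genes, 6 rose and 5 fell, and 6 rose and 5 fell when adjusted over the list alone (camera adjusted p = 0.375, adjusted p = 0.758 with an estimated correlation). B2M, the light chain, rose from 248 to 1055 TPM (log2 change 2.13 ± 0.19) and HLA-A fell from 209 to 99.8 TPM (log2 change -1.05 ± 0.22). Of the other lists at this span, 6 fell and 2 did not pass of 8 Activin and Nodal targets (camera adjusted p = 0.0513), 10 rose, 5 fell and 1 did not pass of 16 cytotrophoblast markers (camera adjusted p = 0.0611), 2 rose, 9 fell and 1 did not pass of 12 glycolysis genes (camera adjusted p = 0.0970), 8 rose, 3 fell and 6 did not pass of 17 cholesterol synthesis genes (camera adjusted p = 0.140), and 7 rose, 4 fell and 1 did not pass of 12 stress response genes (camera adjusted p = 0.140). In the same way 2 rose and 3 did not pass of 5 HOX genes (camera adjusted p = 0.167), 7 rose and 7 fell of 14 epithelial junction genes (camera adjusted p = 0.199), 3 rose, 11 fell and 4 did not pass of 18 FGF and ERK targets (camera adjusted p = 0.221), 5 rose, 3 fell and 1 did not pass of 9 BMP targets (camera adjusted p = 0.232), 3 rose, 4 fell and 1 did not pass of 8 endothelium and blood genes (camera adjusted p = 0.879), 4 rose, 6 fell and 2 did not pass of 12 imprinted genes (camera adjusted p = 0.996), and 2 fell and 11 did not pass of 13 mitochondrially encoded mRNAs (camera adjusted p = 0.996). The signs of the median, the mean and the camera test differed within a list, or the median was 0, for naive-state, syncytiotrophoblast, pregnancy-specific glycoprotein and cytotrophoblast genes at day 1 against day 0. It was so for syncytiotrophoblast, FGF and ERK, glycolysis and imprinted genes at day 2 against day 1. The same held for naive-state, junction, Activin and Nodal, HOX and glycolysis genes at day 4 against day 2, and for neural crest, endothelium and imprinted genes at day 8 against day 0, and camera called none of these.

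Genes that passed against both day 0 and day 8 at an intermediate day numbered 2806 when higher there and 1493 when lower. LHX5 and IRX1, homeobox factors, were higher at day 1, at 32.2 ± 5.98 and 19.1 ± 0.948 TPM, against 0.210 ± 0.0566 and 0.600 ± 0.0849 at day 0 and 0.375 ± 0.177 and 0.0350 ± 0.0495 at day 8. SAMD11 reached 27.9 ± 4.11 and CFC1, a Nodal co-receptor family member, 39.3 ± 2.04 TPM at day 1, against 0.0750 ± 0.0354 and 0.135 ± 0.134 at day 8. HAND1 peaked at day 2 with 463 ± 45.2 TPM, and STOM, a membrane protein, with 404 ± 56.9, against 15.4 ± 1.30 and 6.50 ± 0.417 at day 8. H19 peaked at day 4 with 4160.5 ± 748 TPM, between 6.45 ± 1.51 at day 0 and 90.6 ± 0.530 at day 8, and PRRT4 and COL6A6, a collagen VI chain, with 29.1 ± 2.64 and 13.2 ± 1.65. EDNRB and DUSP6 were lower at day 1, at 3.04 ± 0.240 and 2.08 ± 0.417 TPM, than at day 8, at 43.6 ± 2.25 and 26.8 ± 1.03. HSD11B2, the enzyme that inactivates cortisol, was lowest at day 2 with 0.610 ± 0.170 TPM and stood at 517 ± 1.47 at day 8, and SERPINE1, a plasminogen activator inhibitor, was at 21.7 ± 18.1 and 525 ± 10.04. GLRX, a glutaredoxin, and TUBB4A, a tubulin, were lower at day 4, at 1.21 ± 0.481 and 0.140 ± 0.198 TPM, than at day 0, at 13.9 ± 2.45 and 13.0 ± 0.962.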

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

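A group of 6 panel genes and 3 lists were called in opposite directions at different steps, and the difference between both steps was tested within the same limma fit or by camera. The pairs of steps and these tests were chosen only after the results were seen, and since each pair was picked for calls with opposite signs, the tests of the difference add no evidence beyond those calls. CDX2, the trophectoderm factor, rose from day 1 to day 2 (log2 change 3.49) and fell from day 2 to day 4 (-3.23; limma difference -6.72, adjusted p = 8.52e-05). ISL1, the amnion factor, rose from day 0 to day 1 (log2 change 2.12) and fell from day 2 to day 4 (-3.47; limma difference -5.59, adjusted p = 2.87e-06). GABRP rose from day 1 to day 2 (log2 change 5.39) and fell from day 4 to day 8 (-3.03; limma difference -8.42, adjusted p = 7.13e-06). KRT7 rose from day 1 to day 2 (log2 change 4.88) and fell from day 4 to day 8 (-0.63; limma difference -5.50, adjusted p = 3.14e-06). SDC1, the syndecan, fell from day 1 to day 2 (log2 change -1.09) and rose from day 2 to day 4 (5.61; limma difference 6.70, adjusted p = 4.21e-06). HLA-G fell from day 0 to day 1 (log2 change -0.72) and rose from day 2 to day 4 (4.57; limma difference 5.29, adjusted p = 6.01e-06), and the first of these calls was lost without day 0 replicate 2 (adjusted p = 0.157), day 1 replicate 1 (adjusted p = 0.114), day 1 replicate 2 (adjusted p = 0.127), day 8 replicate 1 (adjusted p = 0.0607) or day 8 replicate 2 (adjusted p = 0.0607), in a range from 0.0213 to 0.157 over 13 alternatives. The amnion markers had a median log2 change of 2.32 from day 1 to day 2 and of -1.39 from day 4 to day 8 (median of the members' differences, camera: difference -3.91, adjusted p = 5.66e-06, and adjusted p = 0.139 with an estimated correlation). The 5 tested HOX genes had medians of 1.91 and -1.76 at the same steps (camera: difference -3.49, adjusted p = 7.20e-04, and adjusted p = 0.139 with an estimated correlation), and as the level filter kept them only through days after day 1, the first of these is no independent evidence of a rise. The 13 mitochondrially encoded mRNAs had medians of -0.38 and 0.30 there (camera: difference 0.85, adjusted p = 0.00149, and adjusted p = 0.517 with an estimated correlation). Beside the last, mitochondrial transcripts took 7.50, 5.74, 4.65 and 6.32% of TPM at days 1, 2, 4 and 8.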

How the results depend on the processing

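All alternatives for counts and lists were planned, and leaving out a library for the values of named genes was a test chosen only after the results were seen. The 13 counts stayed within 1.5 times their reported value with pseudocounts of 0.1 and 0.5, with no filter, after median-of-ratios scaling, quantile normalization or rescaling without mitochondrially encoded genes, and with no variance trend. Asking for an absolute log2 change of at least 1 left 741 genes higher and 526 lower at day 1 than day 0, 948 and 1129 at day 2 than day 1, 1739 and 1240 at day 4 than day 2, 1504 and 1541 at day 8 than day 4, and 3522 and 4589 at day 8 than day 0. It left 9461 genes that differed between any of the days, 1024 higher and 367 lower at an intermediate day, which follows from the added criterion. With a mean TPM of at least 5, 1583 genes were lower at day 2 than day 1, among fewer genes tested. A fit to the compared days alone called 538 higher and 314 lower genes at day 1 than day 0, from 4 libraries. Median-of-ratios scaling moved the median log2 change of all tested genes from -0.10 to -0.04 at day 4 against day 2, from -0.11 to 0.01 at day 8 against day 4 and from -0.25 to -0.06 at day 8 against day 0, and the share of called genes that were higher from 45.8 to 52.8%, from 41.3 to 56.0% and from 41.1 to 48.9%. That follows from its construction, since it sets the typical gene near 0, and TPM cannot show which scaling fits the RNA content of the cells. The side with more genes turned in several settings at day 2 against day 1, among them quantile normalization (2385 higher and 2536 lower), and at day 1 against day 0 with a mean TPM of at least 5 (1536 higher and 1554 lower).

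Leaving out each library in turn, where the lone library left in a day was taken to vary like the other days, gave these ranges. Day 1 against day 0 had 825 to 1839 genes higher and 514 to 1737 lower. Day 2 against day 1 had 1485 to 2544 genes higher and 1317 to 2512 lower. Day 4 against day 2 had 2877 to 3685 genes higher and 2740 to 4393 lower. Day 8 against day 4 had 2678 to 3590 genes higher and 3720 to 5048 lower. Day 8 against day 0 had 4881 to 5476 genes higher and 6756 to 7811 lower. Genes that differed between any of the days ranged 13692 to 14816, transiently higher genes 2261 to 2662 and transiently lower genes 1077 to 1446. Each of these fits has fewer samples, and beyond that the cause was not tested. Of 810 named gene calls, 28 were lost with a pseudocount of 0.1, 28 after median-of-ratios scaling, and between 32 (without day 0 replicate 1) and 81 (without day 1 replicate 2) with a library left out.

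Of 47 list calls, 47 were lost with an estimated inter-gene correlation, 3 by fry, 2 with a pseudocount of 0.1, 1 with no filter, 1 after median-of-ratios scaling, 2 after quantile normalization, 2 with the compared days alone and at most 4 with a library left out. Lists not called before were called in 52 cases by fry, 26 with no filter, 12 without day 2 replicate 1, and at most 9 under any other alternative. With a mean TPM of at least 5, 8 of the 43 calls whose lists could still be tested were lost, and 45 calls could be tested without mitochondrially encoded genes. A call by camera depends on the preset correlation in each of these lists. The sign reversed in 3 results. By fry, which tests whether the members move one way on balance without comparing them with other genes, the amnion list at day 4 against day 2 (adjusted p = 0.00952) and the neural crest list at day 8 against day 0 (adjusted p = 0.0378) had the direction down, where camera had the direction up and called neither, and the cause was not tested. The medians of their members, which neither test sets, were 0.46 and -0.69. DSG2, a desmosomal cadherin, had a log2 change of 0.044 at day 8 against day 0 after median-of-ratios scaling (adjusted p = 0.588), which follows from that scaling, since its factors raised the log2 changes of this span by about 0.25.

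The replicate numbers gave little sign of pairing the samples. The correlation of the replicate 1 deviations between days, across genes, lay between -0.04 and 0.15, and 1 of 10 was over 0.1, that of days 1 and 2. Small effects shared by a replicate number cannot be excluded in this way. With the replicate number as a block, 1784 genes were higher and 1683 lower at day 1 than day 0, 2333 and 2376 at day 2 than day 1, 3571 and 4288 at day 4 than day 2, 3498 and 4978 at day 8 than day 4, and 5404 and 7752 at day 8 than day 0. The block kept 47 of 47 list calls and lost 15 of 810 named gene calls. Depth sets a limit that TPM do not show, so levels near 0 are given as listed and not as absence.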

Other observations

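Gene families outside the lists, and the genes PABPC1, EEF1A1, CD274, TXNIP and NOS2, were chosen after their values were seen. The tests of transcript length and of GC content below were planned before their results were seen, and the other tests were chosen only after. From day 0 to day 8, 78 of 80 genes of cytosolic ribosomal proteins fell and 2 rose (median log2 change -0.99, or -0.74 after median-of-ratios scaling), as did 69 of 78 of mitochondrial ribosomal proteins, while 6 rose (median -0.85, or -0.60 after median-of-ratios scaling). Of the NDUF genes of respiratory complex I, 38 of 47 fell and 2 rose (median -0.90, or -0.65 after median-of-ratios scaling), and of the SNRP genes of the spliceosome, 12 of 12 fell (median -1.40, or -1.15 after median-of-ratios scaling). Of the genes of the vacuolar proton pump, which acidifies lysosomes, 16 of 23 rose and 7 fell (median 1.07, or 1.32 after median-of-ratios scaling). PABPC1, the main poly(A)-binding protein of the cytoplasm, rose from 2252 ± 249 to 8393 ± 301 TPM (log2 change 1.90 ± 0.08, limma adjusted p = 2.92e-07), while EEF1A1, the translation elongation factor, fell from 11832 ± 1284 to 6754 ± 272 TPM (log2 change -0.81 ± 0.08, limma adjusted p = 3.76e-05). CD274, the immune checkpoint ligand PD-L1, rose from 0.0400 ± 0.0141 to 249 ± 21.7 TPM (log2 change 7.91 ± 0.17, limma adjusted p = 1.04e-08). NOS2, the inducible nitric oxide synthase, rose from 0.525 ± 0.163 to 358 ± 26.2 TPM (log2 change 7.88 ± 0.14, limma adjusted p = 4.99e-09), and TXNIP, an inhibitor of thioredoxin and glucose uptake, rose from day 4 to day 8 from 10.1 ± 1.27 to 138 ± 4.66 TPM (log2 change 3.66 ± 0.17, limma adjusted p = 6.46e-06). The signs of these family medians and gene changes held after median-of-ratios scaling.

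In these data 187 of 239 ribosomal, respiratory chain and splicing genes fell from day 4 to day 8 and 10 rose (median log2 change -0.65). Their transcripts were short (median 785 nt against 1854 nt), yet 1000 sets of genes matched for length and level had a median of -0.28 (95% of sets from -0.38 to -0.19), and the family lay a further -0.37 below, with 0 of 1000 sets as low. Matching for GC content (50.3% in both) gave sets with a median of -0.19 (from -0.29 to -0.09), and the family lay -0.46 below, again with 0 of 1000 sets as low. The families were chosen after their values were seen, so these 0 of 1000 sets are no independent evidence against length or GC content. They show only that genes of like length or GC content fell less. After median-of-ratios scaling the family median was -0.45 and 157 of the 187 genes that fell still passed. The decrease thus held relative to the typical gene. TPM cannot show which scaling fits the RNA content of the cells, so scaling stays open as a cause. The SE of that median, 0.0308, was taken over the 239 genes as if independent, and not between libraries. The difference in cell state between the days stays open, and no biological explanation was tested.

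CCNB1, cyclin B1, and RRM2, the ribonucleotide reductase subunit, rose from day 4 to day 8 while most other proliferation genes fell. Median-of-ratios scaling gave log2 changes of 2.08 ± 0.06 for CCNB1 and 1.31 ± 0.14 for RRM2. As this scaling pushes the changes of this step upward, it could only enlarge a rise and does not decide on scaling. A larger share of dividing cells would raise other cell cycle genes too. But 30 of them outside the list had a median log2 change of -0.64 (-0.44 after median-of-ratios scaling), and 22 fell and 3 rose. As a share of transcripts, that argues against such a larger share of dividing cells. Most genes of the related list had already been seen to fall, so these 30 add little independent evidence. The SE of the median of -0.64, 0.110, was taken over these genes as if independent, and not between libraries. Reads shared with pseudogene copies stay open: the pseudogene entries (3 for RRM2, 0 for CCNB1) changed by 0.0250 TPM in sum, 0.00195% of the gain of 1281 TPM, which does not show how reads were divided between copies. The difference in cell state between the days stays open as well, and no other biological explanation was tested.

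From day 2 to day 4, 8 of the 18 mesenchyme and fibroblast genes rose, among them LUM, COL3A1, DCN and COL5A1, all parts of the extracellular matrix. Fibroblasts, including carried-over feeders, which are mouse cells, would bring their collagen transcripts together, but of 8 collagen genes in the list 5 rose and 2, COL6A1 and COL6A2, fell (log2 changes -1.78 ± 0.14 and -1.48 ± 0.14). Fibroblasts stay open, since a high level of a collagen gene at day 2 can hide what a small share of them would add. After median-of-ratios scaling 8 of 8 members that rose still passed. That scaling pushes the changes of this step upward, so it could only enlarge a rise and does not decide on scaling. The difference in cell state between the days stays open too, and no other biological explanation was tested.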
